A study of Mus musculus with 6 samples.

How the data were processed

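Nuclei of the mouse hippocampus (tissue label: hippocampus, DG) were profiled by droplet-based 3' RNA sequencing of single nuclei. The series holds 6 libraries, each made from the pooled tissue of 5 male C57BL/6J mice aged 12 weeks, 30 mice in all. Mice received vehicle or CI-994, an inhibitor of the class I histone deacetylases (HDACi in the labels), at 30 mg/kg 1 h before the exposure, and were killed 1 h after it. In contextual fear conditioning (CFC) the exposure included 2 foot shocks of 0.2 mA. The Context mice saw the chamber with no shock. There were 2 Veh-CFC, 2 HDACi-CFC, 1 Veh-Context and 1 HDACi-Context libraries. The title and treatment label of the Veh-Context library say vehicle while its description says HDACi. It was kept as the library labelled Veh-Context on its title, and its values went with vehicle.

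The deposited matrices hold raw counts of unique molecular identifiers (UMI counts) per gene and nucleus barcode, without normalization, as whole numbers. Per the file headers they were made with Cell Ranger 3.0.1 for the 4 CFC libraries and 3.0.2 for the 2 Context libraries. Per the labels the genome build was mm10, and the authors used Seurat 4.0.3 in later steps whose values are not in these files. Whether reads in introns were counted is not stated. The submitters' protocol text speaks of 4 pooled libraries, so the Context libraries may have been made and sequenced apart. The files list only barcodes called as cells, and no empty droplets, so free RNA could not be measured directly. Gene IDs were looked up in GENCODE M21, where 30934 of the 31053 IDs (99.6%) matched, and coordinates are those of GRCm38, the same assembly as mm10.

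The 6 matrices held 30323 barcodes. Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept, and doublets called by Scrublet within each library (expected rate 0.06) were removed, which left 26839 nuclei. Counts were log-normalized to 10000 per nucleus with scanpy 1.11.5. The 2000 most variable genes, chosen without the activity gene lists and the list of HDAC inhibitor-induced genes and scaled within each library, 30 principal components and 20 neighbours gave 30 clusters by the Leiden method (leidenalg 0.10.2, resolution 1.0, seed 0). Clusters were named from marker lists written before the data were examined, when the best list had a mean log2 ratio of at least 0.8, at least 3 markers detected in 0.10 of nuclei, and a member among the 10 leading genes of the cluster, with no other list holding more of these. Names end in "-like" because they rest on markers alone. Clusters 8, 9, 13, 18, 23, 26 and 29 met no rule and stayed unnamed.

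For each class with at least 30 nuclei in each library, UMIs were summed per library and analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling and the two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested in that class. A gene was called at an adjusted p below 0.05. The drug comparison used the 4 CFC libraries with group as the term. The comparison of CFC with Context used all 6 libraries with drug as covariate. The difference of the drug effect between DG granule-like and each other class was tested as an interaction with library as a block, in a joint fit of the 2 classes with its own TMM factors. The Context pair has 1 library per group, so it had no test and log2 ratios carry 95% counting intervals. Named genes have them also below 100 UMIs. The highest and lowest ratios and the shared signs were taken from genes with at least 100 UMIs. Values per gene are CPM (UMIs of the gene per library total, set to the same total in each library) after TMM scaling, as mean ± SD over 2 libraries, and SE is that of the log2 fold change. No exact permutation test was run on class shares, since 2 libraries against 2 give a smallest two-sided p of 0.333, and no model was fitted to them. The 23 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 (preset correlation 0.01) in each class where at least 4 members were tested, adjusted over 263 list and class pairs, of which 23 are those of all nuclei pooled. Each list was also tested with an estimated correlation and with fry. The estimated correlation rests on the few residual degrees of freedom that 2 libraries per group leave. No list and class pair was called with it, so a failure there says little about a given list.

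Genes named by rule were, in the DG granule-like class, the 10 with the highest and the 10 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 5 and both HDACi-CFC libraries on the same side of both Veh-CFC libraries. In each other class they were the 3 highest and 3 lowest by the same rule. Gene models without a name were counted but not named, and some genes, with a test made on one of them, are not reported here. All class I histone deacetylases, 8 activity genes (Fos, Fosb, Arc, Egr1, Npas4, Nr4a1, Bdnf, Homer1) and up to 4 members per list were named as well. Genes outside this rule are marked as chosen after their values were seen.

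The replicate numbers are shared by the groups, but no label says that a number marks a shared day, so they were not used as pairs. Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, limma-voom, no low-count filter, the replicate number as a block, leave-one-out fits, all 6 libraries, doublets kept, stricter and looser filters on nuclei, equal numbers of nuclei, thinned counts, a filter on genes of other classes, other clustering resolutions and other thresholds. Added after the data were seen were library-size scaling, scaling per nucleus, DG clusters 0 and 3 alone, the HDACi libraries alone for conditioning and leave-one-out fits for the class differences. The test was tested on simulated data, negative binomial counts drawn around the mean levels of 15532 genes in DG granule-like nuclei. It recovered 44% of genes changed 1.5-fold, 84% changed 2-fold and 96% changed 3-fold, with 7 false calls among 128, and called 0 genes when none had been changed. In astrocyte-like nuclei with 8445 genes the shares were 10%, 26% and 80%. The simulations used 1 common dispersion and changed 50 genes at each fold, far fewer than were called in the data. These shares therefore do not carry over to the data.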

Results

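UMI counts per gene were measured in nuclei of mouse hippocampus in 6 libraries. After contextual fear conditioning there were 2 libraries from vehicle-treated mice (Veh-CFC) and 2 from mice given the class I HDAC inhibitor CI-994 (HDACi-CFC). After exposure to the context without shock there was 1 library of each treatment. Total UMIs were 27168385 and 37732552 in Veh-CFC, 24508202 and 39480383 in HDACi-CFC, 39303114 in the library labelled Veh-Context and 45570814 in HDACi-Context. In the same order, the kept nuclei numbered 3661 and 4471, 3573 and 4901, 4899, and 5334. Their median depth was 5955 and 6808 UMIs in Veh-CFC and 5368 and 6348 UMIs in HDACi-CFC.

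The nuclei fell into neuronal, glial and vascular classes by their markers. DG granule-like nuclei, with Stxbp6 and Dsp among the leading genes of their larger cluster, made up 31.4% ± 3.64 (SD, n = 2) of nuclei in Veh-CFC and 31.1% ± 0.882 (n = 2) in HDACi-CFC. CA1-like nuclei made up 15.8% ± 0.522 and 17.0% ± 0.745, CA3-like nuclei 3.99% ± 0.302 and 4.93% ± 0.126, and interneuron-like nuclei 6.10% ± 0.912 and 6.02% ± 0.516. Oligodendrocyte-like nuclei made up 12.7% ± 0.253 and 11.7% ± 1.32, astrocyte-like nuclei 4.19% ± 0.607 and 5.27% ± 0.285, and microglia-like nuclei 5.13% ± 0.338 and 5.32% ± 0.077. Subicular-like nuclei made up 2.41% ± 0.652 and 1.33% ± 0.608, with 32 nuclei in HDACi-CFC replicate 1. Unnamed clusters held 11.6% ± 0.926 and 10.5% ± 0.497. No exact permutation test of the shares was run, since its smallest two-sided p for 2 libraries against 2 is 0.333.

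The series asks how the HDAC inhibitor changes transcription after fear conditioning, cell type by cell type. Rankings here follow the naming rule, among called genes with a mean log2 CPM of at least 5 and the 2 groups apart. The genes with the largest increases in DG granule-like nuclei included Igsf3, an immunoglobulin superfamily member, Tbl1x, a subunit of the NCoR corepressor complex, Nefm, a neurofilament subunit, and Syn1, a synaptic vesicle protein. Igsf3 (ENSMUSG00000042035, mm10 chromosome 3, 101377083 to 101463059) went from 44.6 ± 3.46 CPM (SD, n = 2) to 175.2 ± 4.24 CPM (n = 2), 3.95-fold, with an adjusted p of 4.13e-12. Tbl1x (chromosome X, 77511013 to 77662983) rose 3.88-fold, Nefm 3.65-fold and Syn1 (chromosome X, 20860511 to 20921004) 3.08-fold, from 150.2 ± 2.19 to 462.6 ± 12.8 CPM. Gpc4, a glypican, rose 3.23-fold, from 186.8 ± 3.75 to 602.7 ± 15.1 CPM. The others of the 10 highest were Arid5b (log2 fold change 1.83), Timp4 (1.70), Hmgcll1 (1.65), Fam49a (1.62) and Dbpht2 (1.59). Among genes that met the naming rule, Trim37 (ENSMUSG00000018548, chromosome 11, 87127077 to 87220683), a ubiquitin ligase, fell the most, from 103.4 ± 3.04 to 21.88 ± 0.332 CPM, 4.74-fold lower with an adjusted p of 4.13e-12. Terf1, which binds telomere repeats (chromosome 1, 15805646 to 15844052), was 4.04-fold lower and Gmcl1 4.32-fold lower. Wnk1, a kinase that regulates ion transport, fell from 141 ± 0.636 to 45.8 ± 0.742 CPM. Gdpd1 (−1.80), Pou2f2 (−1.70), Zfp704 (−1.68), Rspry1 (−1.68), Smc6 (−1.68) and Tmem55a (−1.62) completed the 10 lowest by this rule.

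**Figure D1:**
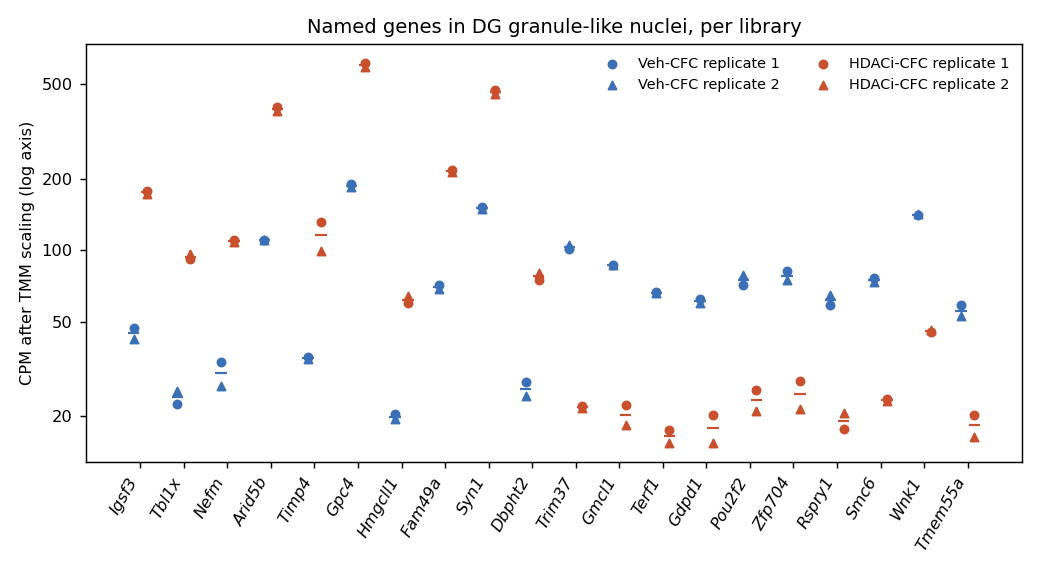
CPM per library (log axis) of the 10 genes with the highest and the 10 with the lowest log2 fold change among those that met the naming rule in DG granule-like nuclei, in the 2 Veh-CFC and 2 HDACi-CFC libraries, with dashes at the means. Both HDACi-CFC libraries lie on the same side of both Veh-CFC libraries for each gene, as the rule for naming them required.

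Among 15532 genes tested in DG granule-like nuclei, 3685 were higher and 4092 lower with the inhibitor, 50.1%, of which 835 and 1442 differed by more than 2-fold. TMM scaling sets the balance of directions: with library-size scaling the median log2 change shifted by −0.363 and the counts were 1559 higher and 7134 lower, and per nucleus the shift was −0.515 and the counts were 640 and 7199. Cluster 3 held 23.4% and 21.9% of the DG granule-like nuclei in Veh-CFC and 14.7% and 12.1% in HDACi-CFC, and cluster 3 alone, a fit added after the data were seen, gave 4193 calls. Directions below are relative to the TMM median unless said otherwise, and each group holds 2 libraries of 5 pooled mice.

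Of the 4 class I histone deacetylase genes 1 was called with TMM scaling. Among the class I histone deacetylases, Hdac1 rose 2.06-fold, from 69.82 ± 1.6 to 143.7 ± 8.63 CPM (SD, n = 2 each, adjusted p = 5e-09). Hdac2 (log2 fold change −0.21, adjusted p = 0.168), Hdac3 (0.24, adjusted p = 0.0689) and Hdac8 (0.13, adjusted p = 0.137) did not pass the test. Hdac3 lay below 0 with library-size scaling (−0.12) and per nucleus (−0.27) without a call. Hdac8 was called lower with library-size scaling (−0.23, adjusted p = 0.0101) but not per nucleus (−0.38, adjusted p = 0.0593). Hdac2 was called lower with both (−0.57 and −0.72). Without HDACi-CFC replicate 1 Hdac3 was called higher (0.35, adjusted p = 0.00631). The class I list had 1 member higher and 0 lower of 4 (1 and 0 adjusted over the list alone), a median of 0.187 and a camera adjusted p of 0.367. Of 14 other deacetylases and sirtuins, 5 rose, among them Hdac5 (1.31) and Hdac7 (0.57, lost with library-size scaling), and 4 fell, among them Sirt1 (−1.47) and Sirt7 (−0.61), with 5 and 4 adjusted over the list alone. That list's median was −0.0105 while its test pointed up, with an adjusted p of 0.885. Of 15 histone acetyltransferase genes 1 rose and 8 fell (1 and 8 adjusted over the list alone), among them Hat1 (−1.09), Ep300 (−0.82) and Clock (−0.55). Ncoa1 (0.40) was the member that rose, and it lost its call with library-size scaling and lay at −0.12 per nucleus. The acetyltransferase list had a median of −0.369 and an adjusted p of 0.0366 (adjusted p = 0.49 with an estimated correlation), 0.052 without Veh-CFC replicate 2 and 0.115 without HDACi-CFC replicate 2. Of 26 genes of class I corepressor complexes 11 rose, among them Tbl1xr1 (log2 fold change 0.74), and 5 fell, Sin3a among them (2.45-fold lower), with 11 and 5 adjusted over the list alone and an adjusted p of 0.176. With library-size scaling the members called higher and lower were 1 and 2 (class I), 1 and 7 (other deacetylases), 0 and 13 (acetyltransferases) and 5 and 10 (corepressors). Per nucleus they were, in the same order, 1 and 1, 1 and 7, 0 and 13, and 2 and 10.

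Neuronal activity genes were higher with the inhibitor as lists, though the classic markers Fos, Arc and Egr1 did not pass the test. Of 20 immediate early genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), among them Btg2 (log2 fold change 1.28), Jun (1.04), Gadd45g (0.89) and Nr4a1 (2.37-fold, adjusted p = 6.33e-05). The list's median was 0.770 and its adjusted p 0.00589 (adjusted p = 0.49 with an estimated correlation). Of 24 late activity-regulated genes 16 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.577 and an adjusted p of 0.000521 (adjusted p = 0.49 with an estimated correlation). Among these were Bdnf, which encodes a neurotrophin (1.27, adjusted p = 1.7e-10), Mbnl2 (1.40), Rasgrp1 (0.92) and Ptgs2 (1.86). Npas4 went from 1.099 ± 0.295 to 3.328 ± 1.55 CPM (1.45, adjusted p = 0.00627), on 7 and 17 UMIs in Veh-CFC and 26 and 20 in HDACi-CFC. Its call was lost without HDACi-CFC replicate 1 (0.95, adjusted p = 0.125). Fos (0.98, adjusted p = 0.185), Arc (0.16, adjusted p = 0.678), Egr1 (0.63, adjusted p = 0.149) and Homer1 (0.17, adjusted p = 0.0965) were not called, and Fosb had too few counts to be tested. Without Veh-CFC replicate 2, Fos (3.42, adjusted p = 0.0138) and Arc (1.23, adjusted p = 0.000499) were called, and without Veh-CFC replicate 1 Arc was −0.30. Fos had 1 and 15 UMIs in the Veh-CFC libraries. Arc and Homer1 lay below 0 with library-size scaling (−0.20 and −0.19) and per nucleus (−0.34 and −0.34), and Npas4, Gadd45g and Rasgrp1 lost their calls per nucleus. With library-size scaling 7 immediate early genes rose and 3 fell, and 11 and 4 late genes, and per nucleus these were 4 and 3, and 4 and 4.

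With TMM scaling, most called genes of synapses and excitability were higher in DG granule-like nuclei. Of 32 presynaptic genes 22 rose and 4 fell (22 and 4 adjusted over the list alone), among them Syn1 (log2 fold change 1.62), Syn2 (2.82-fold), Nsf (1.22) and Snap25 (0.97), with a median of 0.482 and an adjusted p of 0.00151. Of 50 synaptic adhesion and scaffold genes 38 rose and 6 fell (39 and 6 adjusted over the list alone), among them Epha4 (1.21), Dlgap1 (0.85), Epha7 (0.85) and Dlgap2 (0.69), with an adjusted p of 0.000378. Of 38 voltage-gated channel genes 24 rose and 7 fell (24 and 7 adjusted over the list alone), among them Kcnd3 (1.08), Cacna1e (0.97), Cacna1c (0.94) and Kcnq3 (0.91), with an adjusted p of 0.00301. Of 22 glutamate receptor genes 16 rose and 4 fell (16 and 4 adjusted over the list alone), among them Grin2a (0.94), Gria2 (0.81), Grin2b (0.75) and Gria1 (0.71), with an adjusted p of 0.0128. Of 14 GABA receptor genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), among them Gabbr2 (0.95), with an adjusted p of 0.00915. Of 47 calcium, cAMP and MAPK signalling genes 26 rose and 9 fell (28 and 9 adjusted over the list alone), among them Prkce (1.21), Camk2a (1.05) and Rps6ka2 (1.05), with an adjusted p of 0.00679. Of 38 axon guidance and cytoskeleton genes 24 rose and 4 fell (24 and 4 adjusted over the list alone), among them Dclk1 (1.41), Slit3 (1.03) and Kalrn (0.93), with an adjusted p of 0.000176. With an estimated correlation none of these 7 calls held: the adjusted p was 0.49 for presynaptic, adhesion, GABA receptor and axon guidance genes, 0.495 for glutamate receptors, 0.523 for channels and 0.533 for signalling. That test has few residual degrees of freedom and called no list in any class, so it cannot tell these lists from others. Among random lists of the same expression level the medians of these 7 lists lay at percentiles 37.9 (GABA receptors) to 96.2 (presynaptic), none above the middle 95%. With library-size scaling the members called higher and lower were 13 and 9 (presynaptic), 9 and 11 (adhesion), 12 and 12 (channels), 5 and 6 (glutamate receptors), 3 and 4 (GABA receptors), 15 and 16 (signalling) and 15 and 8 (axon guidance). Per nucleus they were, in the same order, 4 and 8, 1 and 10, 4 and 11, 0 and 4, 1 and 3, 4 and 15, and 6 and 8. The medians of the adhesion, glutamate receptor, GABA receptor and axon guidance lists fell below 0 with library-size scaling, and those of all 7 lists did per nucleus, where Grin2a, Gria1, Grin2b, Gria2, Dlgap1, Epha7, Dlgap2, Kcnq3 and Kalrn lost their calls.

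Most lists rose with TMM scaling: of all 23 in these nuclei, 19 had a median above 0 and 4 below. Over the classes and all nuclei together, camera called 128 list and class pairs higher and 7 lower. Of 15 genes that HDAC inhibitors induce in other cells 8 rose and 0 fell (8 and 0 adjusted over the list alone), among them Stmn4 (log2 fold change 1.47), Hspa2 (0.94), Mt1 (0.76) and Slc17a7 (0.40, lost with library-size scaling and −0.11 per nucleus), with an adjusted p of 0.00679 (adjusted p = 0.569 with an estimated correlation). Of 22 cholesterol synthesis genes 2 rose and 10 fell (2 and 10 adjusted over the list alone), among them Mvd (−1.90), Cyp51 (−1.12) and Msmo1 (−0.63), with an adjusted p of 0.021 (adjusted p = 0.49 with an estimated correlation). Of 15 glucocorticoid-responsive genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them Nr3c1, the glucocorticoid receptor (0.96), with an adjusted p of 0.0222 (adjusted p = 0.569 with an estimated correlation), and 0.122 without HDACi-CFC replicate 2. Of 19 circadian clock genes 7 rose, among them Arntl (1.51) and Hlf (0.97), and 8 fell, among them Clock (8 and 8 adjusted over the list alone), with a median of −0.126, a test that pointed up and an adjusted p of 0.885. Of 18 heat shock genes 5 rose and 2 fell (3 and 2 adjusted over the list alone), with an adjusted p of 0.514. All 13 mitochondrial transcripts rose (13 adjusted over the list alone; adjusted p = 0.0181, 0.0913 without Veh-CFC replicate 2, 0.0785 without HDACi-CFC replicate 1, and adjusted p = 0.634 with an estimated correlation), but all 13, mt-Nd4, mt-Co3, mt-Atp6 and mt-Co1 among them, lost their calls with library-size scaling and per nucleus. Their shares of UMIs overlapped between the groups, at 9653.6 and 5869.8 CPM in Veh-CFC and 9588.3 and 8288.5 CPM in HDACi-CFC. Of 32 ribosomal protein genes 16 rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 0.00308, 0.0815 without HDACi-CFC replicate 2, and adjusted p = 0.592 with an estimated correlation), and their median lay below 0 with library-size scaling. With that scaling the members called higher and lower were 5 and 1 (HDAC inhibitor-induced), 0 and 16 (cholesterol), 6 and 1 (glucocorticoid), 4 and 10 (clock), 1 and 6 (heat shock) and 4 and 3 (ribosomal), and per nucleus 1 and 1, 0 and 16, 2 and 2, 3 and 10, 0 and 6, and 0 and 3.

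Some myelin and astrocyte genes were also higher in DG granule-like nuclei. The myelin list rose in oligodendrocyte-like nuclei too, and the astrocyte list in astrocyte-like nuclei. Free RNA was not measured, so RNA from glia is not excluded as the origin of these transcripts. Of 21 myelin genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them Olig1 (log2 fold change 1.24), Mbp (0.86) and St18 (−0.37), with an adjusted p of 0.00796 (0.0671 without HDACi-CFC replicate 2, and adjusted p = 0.563 with an estimated correlation). Of 23 astrocyte genes 12 rose and 4 fell (12 and 4 adjusted over the list alone), among them Slc1a3 (1.35) and Gys1 (−1.76), with an adjusted p of 0.0421 (0.104 without Veh-CFC replicate 1, 0.0786 without HDACi-CFC replicate 2, and adjusted p = 0.537 with an estimated correlation). Of 15 microglial genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), with an adjusted p of 0.238, and 0.0353 without HDACi-CFC replicate 1. As a share of UMIs in these nuclei, astrocyte markers made up 1114.4 and 1072.2 CPM in Veh-CFC and 1652.2 and 1783.3 CPM in HDACi-CFC, and oligodendrocyte markers 1564.0 and 1540.2 against 2317.1 and 2496.8 CPM. Microglia markers made up 209.45 and 210.62 CPM in Veh-CFC and 180.18 and 204.22 CPM in HDACi-CFC. With library-size scaling 3 myelin genes rose and 2 fell, 8 and 6 astrocyte genes, and 2 and 3 microglial genes, and per nucleus these were 1 and 2, 3 and 6, and 1 and 4.

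CA1-like nuclei had 2692 genes higher and 2990 lower of 14782 tested, CA3-like nuclei 1647 and 1445 of 11610, and interneuron-like nuclei 2056 and 1602 of 12175. With library-size scaling the counts were 1098 and 6224, 741 and 3068, and 875 and 4153. Without Veh-CFC replicate 2 the CA3-like count was 1874. In CA1-like nuclei the largest increases by the naming rule were in Kif21b, a kinesin (log2 fold change 1.72), Gpc4 (1.71) and Efr3a (from 150 ± 12.3 to 445 ± 43.9 CPM, SD, n = 2 each), and the largest decreases in Lcorl (−1.77), Rasa2 (−1.68) and Terf1 (−1.53). In CA3-like nuclei Foxo1, a transcription factor, rose 4.07-fold, Loxl1 3.81-fold and Mettl24 3.67-fold, while Scube1 (−1.79), Odf2 (2.84-fold lower) and Kmt5b, a histone H4 methyltransferase (−1.48), fell. In interneuron-like nuclei Qrfpr (1.88), Timp4 (1.70) and Neb (1.69) rose and Kmt5b (−1.63) and Mcph1 (−1.49) fell. Of 22 late activity-regulated genes 14 rose and 0 fell in CA1-like nuclei (14 and 0 adjusted over the list alone), with an adjusted p of 0.000176 (adjusted p = 0.49 with an estimated correlation). Of 38 channel genes 27 rose and 0 fell in interneuron-like nuclei (27 and 0 adjusted over the list alone), with a median of 0.596, 0.265 with library-size scaling, and an adjusted p of 1.36e-07 (adjusted p = 0.49 with an estimated correlation). With library-size scaling 10 late activity-regulated genes rose and 3 fell, and 18 and 2 channel genes. Random lists matched on expression level were drawn in DG granule-like nuclei alone, so a trend with level was not tested here. With TMM scaling the highest expression quintile had 1386 genes higher and 393 lower in CA1-like nuclei, and 1169 and 160 in interneuron-like nuclei.

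The inhibitor was also accompanied by changes in glia. In astrocyte-like nuclei 1273 genes were higher and 951 lower of 8445, in oligodendrocyte-like nuclei 2035 and 1763 of 9884, in OPC-like nuclei 1191 and 912 of 6923, and in microglia-like nuclei 1446 and 1285 of 6963. With library-size scaling these were 719 and 2096, 969 and 3610, 676 and 1924, and 937 and 1992. In astrocyte-like nuclei Ski, a repressor of TGF-beta signalling, rose from 27.82 ± 2.84 to 175 ± 14.1 CPM (SD, n = 2 each), and the long noncoding RNA Neat1 from 225.6 ± 4.81 to 1071 ± 69.3 CPM. Trp53cor1 (log2 fold change 2.49) rose as well, and Yes1 (−2.22), Gmcl1 (−2.17) and Ipo11 (−2.10) fell. In oligodendrocyte-like nuclei Synpo (2.34), Rnf122 (2.29) and Gng7 (2.24) rose and Hmgxb4 (−2.06) and Tbc1d12 (−1.93) fell. In OPC-like nuclei Trp53cor1 (3.64), Mir670hg (2.77) and Speg (2.60) rose and Fbn2 (−2.45), Rorb (−2.42) and Pde3b (6.84-fold lower) fell. In microglia-like nuclei Sh2d4b had 9.826 and 0 CPM in Veh-CFC and 244.2 and 382.0 CPM in HDACi-CFC (adjusted p = 1.64e-35), AU019990 (3.90) and Kif9 (3.72) rose, and Cep192 (−3.32), Zfp846 (−3.01) and Stam2 (−2.79) fell. Of 23 myelin genes 19 rose and 0 fell in oligodendrocyte-like nuclei (19 and 0 adjusted over the list alone; adjusted p = 1.12e-05, adjusted p = 0.49 with an estimated correlation), and the members Opalin (1.30) and Myrf (1.12) were picked after their values were seen. Of 25 astrocyte genes 18 rose and 2 fell in astrocyte-like nuclei (19 and 2 adjusted over the list alone; adjusted p = 0.000303, adjusted p = 0.495 with an estimated correlation). Of 17 microglial genes 6 rose and 0 fell in microglia-like nuclei (6 and 0 adjusted over the list alone; adjusted p = 0.0132, adjusted p = 0.503 with an estimated correlation). With library-size scaling these counts were 12 and 1, 12 and 2, and 4 and 0. A trend with expression level was not tested for these lists. With TMM scaling the highest expression quintile had 1072 genes higher and 163 lower in oligodendrocyte-like nuclei. It had 690 and 88 in astrocyte-like and 620 and 115 in microglia-like nuclei. Without Veh-CFC replicate 2 the counts called were 1339 in OPC-like and 1436 in microglia-like nuclei, and without HDACi-CFC replicate 2 they were 1350, 1616 and, in astrocyte-like nuclei, 1428.

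The 3 smallest classes tested gave fewer calls with all their nuclei. With at most 40 nuclei per class and library the counts were 222 in subicular-like, 237 in immature neuron-like and 378 in Cajal-Retzius-like nuclei, against 39 (oligodendrocyte-like) to 943 (DG granule-like) in the other classes. With all nuclei, subicular-like nuclei had 681 genes higher and 345 lower of 8727, immature neuron-like nuclei 409 and 198 of 5260, and Cajal-Retzius-like nuclei 218 and 121 of 2375. With library-size scaling these were 261 and 1153, 227 and 455, and 117 and 192. In subicular-like nuclei Abca12 (log2 fold change 2.04), Fhad1 (2.01) and Xylt1 (1.81) rose and Cab39l (−2.41), Ccdc58 (−2.31) and Kmt5b (−2.05) fell. The make-up of this class differed between the groups: cluster 22 held 27.62% and 31.03% of its nuclei in Veh-CFC and 53.12% and 37.21% in HDACi-CFC. In immature neuron-like nuclei Scrt2 (2.58), Gpc4 (2.43) and Disp3 (6.00-fold) rose and Mok (−3.48), Fuca1 (−3.21) and Pus7 (−2.83) fell. In Cajal-Retzius-like nuclei Smoc2 (3.91), Sez6l (3.73) and Ryr2 (3.46) rose and Thoc1 (−4.09), Hjurp (−3.51) and Tmem55a (−2.98) fell. Scrt2 lost its call without Veh-CFC replicate 2 (adjusted p = 0.244), HDACi-CFC replicate 1 (0.0966) or HDACi-CFC replicate 2 (0.372), and Fuca1 without HDACi-CFC replicate 2 (0.0986). Among the Cajal-Retzius-like genes, Smoc2 (adjusted p = 0.0501), Thoc1 (0.0661) and Tmem55a (0.261) lost theirs without Veh-CFC replicate 1, and Thoc1 (0.0847), Hjurp (0.134) and Tmem55a (0.188) without Veh-CFC replicate 2. Tmem55a lost it without HDACi-CFC replicate 1 (0.0877), and Hjurp and Tmem55a without HDACi-CFC replicate 2 (0.105 each). The Cajal-Retzius-like calls numbered 37 without Veh-CFC replicate 1, 47 without Veh-CFC replicate 2 and 0 with the replicate number as a block (edgeR, 609 at an unadjusted p below 0.05, DESeq2 9, limma-voom 76). The subicular-like calls numbered 361 and 269 without Veh-CFC replicates 1 and 2. The immature neuron-like calls numbered 399, 272 and 380 without Veh-CFC replicates 1 and 2 and HDACi-CFC replicate 2.

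**Figure D2:**
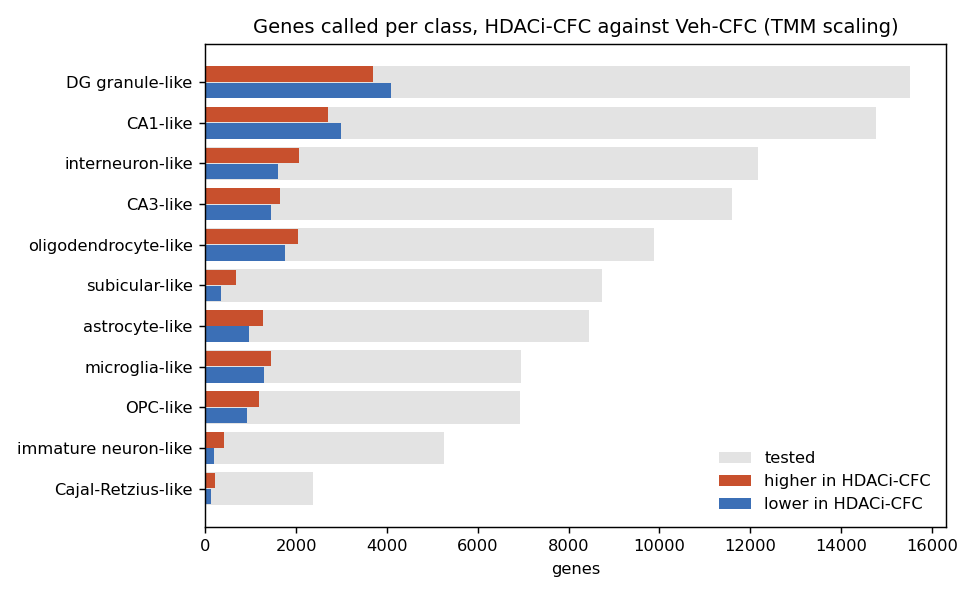
Number of genes called higher and lower in HDACi-CFC than in Veh-CFC in each class (edgeR with TMM scaling, 2 libraries against 2), over the number tested in grey. DG granule-like nuclei, the class with the most nuclei, had 3685 higher and 4092 lower, and Cajal-Retzius-like nuclei 218 and 121.

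The effect of the inhibitor was not the same in each class. Differences come from a joint fit of 2 classes with its own scaling, so they are not exactly those of the separate log2 fold changes. Wnk1 fell in DG granule-like nuclei (log2 fold change −1.62) and rose in microglia-like nuclei (1.11), a tested difference of −2.61 with an adjusted p of 1.14e-59. Trim37 fell by 1.38 more on the log2 scale in DG granule-like than in CA1-like nuclei (adjusted p = 1.7e-11), and Igsf3 rose by 2.31 more in DG granule-like than in astrocyte-like nuclei. Of 303 pairs of a class with the genes named in DG granule-like nuclei as most changed, the class I histone deacetylases or the 8 activity genes, 91 differed from DG granule-like nuclei. The most changed genes were picked by their size in DG granule-like nuclei, which favours smaller changes in other classes. Over all genes tested, the share that differed was 0.505% (immature neuron-like) to 17.5% (oligodendrocyte-like).

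Fewer genes were detected per nucleus with the inhibitor at equal depth. With each DG granule-like nucleus thinned to 3000 UMIs, the median was 1707 and 1716 genes in the Veh-CFC libraries and 1489.5 and 1492 in the HDACi-CFC libraries. It was 1710.5 in the library labelled Veh-Context and 1522 in HDACi-Context. At 1000 UMIs the medians were 719 and 722 in Veh-CFC, 658 and 657 in HDACi-CFC, 716 and 662. The gap between groups was larger than that between replicates, and no test was run.

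**Figure D3:**
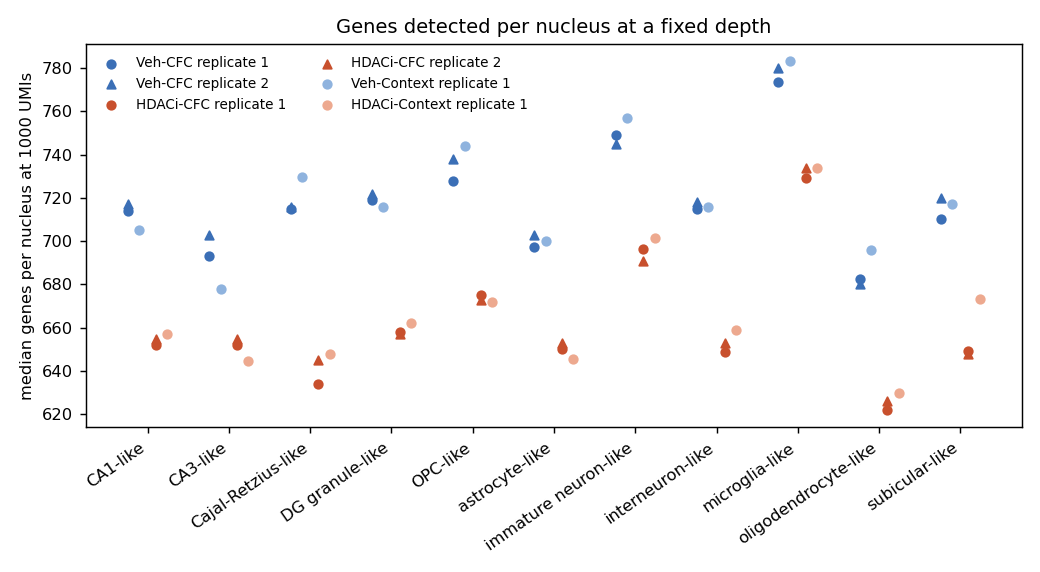
Median number of genes per nucleus at 1000 UMIs (y axis, which does not start at 0) in each of the 6 libraries, by class. In DG granule-like nuclei the HDACi-CFC libraries lie at 658 and 657 and the Veh-CFC libraries at 719 and 722, and both HDACi-CFC libraries lie below both Veh-CFC libraries in all 11 classes.

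Without foot shock, the inhibitor's effect could be set beside that after conditioning in 1 library of each kind. Igsf3 in DG granule-like nuclei had a log2 ratio of 1.86 (95% counting interval 1.69 to 2.04), Nefm 2.02, Bdnf 1.45 (1.34 to 1.55), Hdac1 0.73 (0.60 to 0.86) and Trim37 −1.72 (−1.90 to −1.54). Arc had 1.64 (0.95 to 2.37) on 24 and 71 UMIs, and Nr4a1 0.07 (−0.29 to 0.44) on 127 and 127 UMIs. The highest ratios were those of Neat1 (3.82, on 24 and 323 UMIs), Rps12-ps3 (3.18), Ccdc85b (3.15), Fam198b (3.14) and Sardhos (2.99), and the lowest those of Sgpl1 (−3.24), Mb21d2 (−2.90), Ttl (−2.88), Exog (−2.83) and Gfod2 (−2.82). Of 6912 genes called after conditioning, 6682 (96.7%) had the same sign in the Context pair, and the correlation across genes, which are not independent replicates, was 0.924. Intervals cover counting error only, there are no replicates, and the library labelled Veh-Context is described as HDACi in another field of its labels, while its genes per nucleus (1710.5 at 3000 UMIs) lay with those of Veh-CFC.

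**Figure D4:**
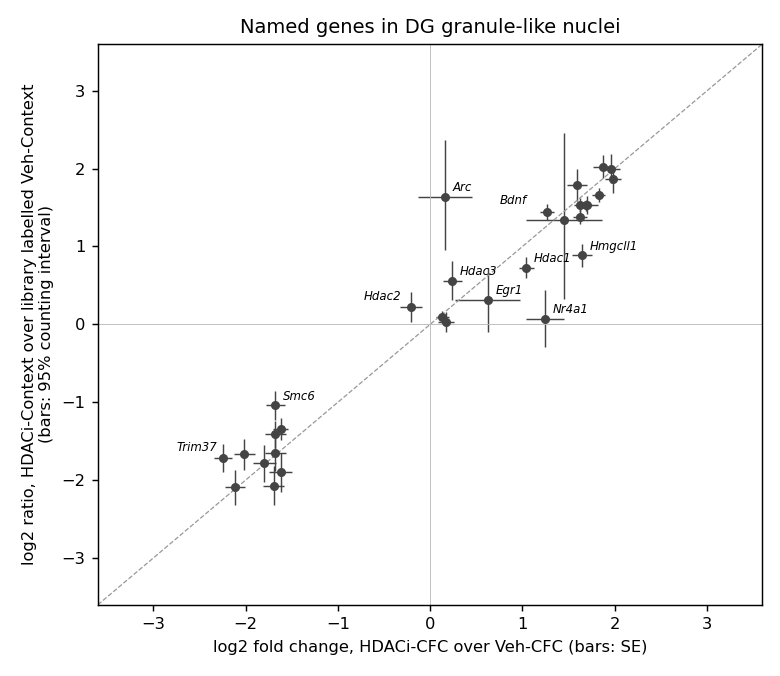
Log2 ratio of HDACi-Context to the library labelled Veh-Context (y axis, 1 library each, bars 95% counting intervals) against log2 fold change of HDACi-CFC over Veh-CFC (x axis, 2 libraries each, bars SE) for the named genes in DG granule-like nuclei, with the line of equal values. Trim37 lies at −2.24 and −1.72, and Nr4a1 near 0 on the y axis.

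Setting conditioning against context asks which genes differ after shock. Matk, a tyrosine kinase, in DG granule-like nuclei had 419.4 ± 57.6 CPM (SD, n = 4) in CFC and 97.46 ± 27.2 CPM (n = 2) in Context (adjusted p = 5.58e-12). The SDs in this paragraph span both treatments, and Context holds 1 library of each. Matk had 366.5 and 374.3 CPM in Veh-CFC and 455.1 and 481.5 CPM in HDACi-CFC. Ctxn1 (log2 fold change 1.80), Telo2 (1.78), Dennd6b (1.70) and Clasrp (1.66) were higher in CFC too. Cmss1 had 46.74 ± 6.96 CPM in CFC and 858.7 ± 168 CPM in Context (adjusted p = 2.88e-13), and AY036118 (−3.29), Pde1c (−2.68) and Shisa3 (−2.27) were lower too. Arc was higher in CFC (1.44, adjusted p = 0.00319), a call lost with DESeq2 (adjusted p = 0.0575) and without the Veh-Context library (0.84, adjusted p = 0.0597; 2.34 without HDACi-Context), and Egr1 lower (−1.60, adjusted p = 3.39e-05). Fos (0.32), Fosb (−1.82), Npas4 (0.47), Nr4a1 (−0.47), Bdnf (−0.10) and Homer1 (0.10) were not called, and Nr4a1 was called lower in the vehicle libraries alone (−1.06) and without HDACi-CFC replicate 2 (−0.63, adjusted p = 0.046). Fos (−0.30 without HDACi-Context), Nr4a1 (0.08 without Veh-Context) and Bdnf (0.01 without HDACi-Context) changed sign. Of 32 ribosomal protein genes 1 was higher and 23 lower (1 and 24 adjusted over the list alone; adjusted p = 4.46e-06, adjusted p = 0.965 with an estimated correlation), and of 13 mitochondrial transcripts 0 were higher and 10 lower (0 and 10 adjusted over the list alone; adjusted p = 0.0423, adjusted p = 0.965 with an estimated correlation). The mitochondrial list pointed the other way, without being called, in microglia-like (7 higher and 0 lower of 11, adjusted p = 0.0853), OPC-like (5 and 0 of 11, adjusted p = 0.0867), astrocyte-like (4 and 1 of 12, adjusted p = 0.284) and immature neuron-like nuclei (2 and 0 of 11, adjusted p = 0.536). In all, 3524 genes were higher and 3749 lower of 17826 tested, 7042 called in the vehicle libraries alone and 5135 in the HDACi libraries alone, where the 1 Context library was taken to vary like the others. Other classes had 3208 higher and 3454 lower (CA1-like), 2417 and 2222 (CA3-like), 2081 and 1984 (interneuron-like), 847 and 1168 (oligodendrocyte-like), 762 and 986 (subicular-like), 461 and 718 (microglia-like), 453 and 651 (astrocyte-like), 360 and 562 (OPC-like), 199 and 345 (immature neuron-like) and 29 and 90 (Cajal-Retzius-like). Without the Veh-Context library the counts were 2843 in CA3-like, 2365 in interneuron-like, 1323 in oligodendrocyte-like, 577 in subicular-like, 687 in microglia-like, 517 in astrocyte-like, 501 in OPC-like and 270 in immature neuron-like nuclei. Without HDACi-Context they were 2683 in interneuron-like, 1312 in oligodendrocyte-like, 1018 in subicular-like, 540 in microglia-like, 583 in astrocyte-like, 378 in OPC-like, 93 in immature neuron-like and 16 in Cajal-Retzius-like nuclei. Without Veh-CFC replicate 1 they were 1128 in subicular-like and 75 in Cajal-Retzius-like nuclei, and without Veh-CFC replicate 2 they were 44 in Cajal-Retzius-like nuclei. The 2 Context libraries went through another Cell Ranger version, so conditioning and a library batch cannot be told apart.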

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

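The drug effect differed between DG granule-like nuclei and each other class by a test of the difference itself. Genes that differed numbered 2645 against CA1-like, 2158 against CA3-like, 2243 against interneuron-like, 2597 against oligodendrocyte-like, 1731 against microglia-like, 1437 against astrocyte-like, 1314 against OPC-like, 581 against subicular-like, 108 against Cajal-Retzius-like and 75 against immature neuron-like nuclei. With at most 40 nuclei per class and library they numbered, in the same order, 61, 81, 58, 7, 33, 41, 198, 103, 102 and 5. With all nuclei, 16.5% of genes tested differed against CA1-like and 0.505% against immature neuron-like nuclei. The correlation of log2 fold changes with DG granule-like nuclei was 0.758 and 0.682 there, and lowest in microglia-like nuclei (0.417). The numbers of genes that differed therefore do not rank the classes by likeness. The fits without 1 library were chosen after these counts were seen. Without Veh-CFC replicate 1 the counts were 1087 for microglia-like, 935 for astrocyte-like, 721 for OPC-like, 124 for subicular-like, 55 for Cajal-Retzius-like and 36 for immature neuron-like nuclei. Without Veh-CFC replicate 2 they were 1702 for CA1-like, 1234 for CA3-like, 1057 for interneuron-like, 1586 for oligodendrocyte-like, 769 for microglia-like, 938 for astrocyte-like, 680 for OPC-like, 124 for subicular-like, 23 for Cajal-Retzius-like and 20 for immature neuron-like nuclei. Without HDACi-CFC replicate 1 the astrocyte-like count was 491. Without HDACi-CFC replicate 2 they were 1205 for CA3-like, 1403 for interneuron-like, 1455 for oligodendrocyte-like, 879 for microglia-like, 368 for astrocyte-like, 728 for OPC-like and 44 for immature neuron-like nuclei.

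Among 31 genes (those named as most changed in DG granule-like nuclei, the class I histone deacetylases and the activity genes), 2 were called in opposite directions in DG granule-like nuclei and another class, with the difference itself called. The differences come from the joint fit of the 2 classes and the log2 fold changes from separate fits, so they do not subtract exactly. Spread is pooled over genes within each joint fit, so the sizes of the p-values cannot be compared between classes. Rspry1 fell in DG granule-like nuclei (log2 fold change −1.68) and rose in OPC-like nuclei (0.78), a difference of −2.36 with an adjusted p of 3.76e-27. Wnk1 fell in DG granule-like nuclei (−1.62) and rose in microglia-like nuclei (1.11), a difference of −2.61 with an adjusted p of 1.14e-59, and in oligodendrocyte-like nuclei (0.25), a difference of −1.996 with an adjusted p of 4.31e-32. Genes named in other classes alone are not in that count, and among those that did the same were Xylt1 (−1.05 in DG granule-like and 1.81 in subicular-like nuclei, a difference of −2.75), Cab39l (−2.18 and 0.91 in oligodendrocyte-like, −3.22), Rasa2 (−2.25 and 0.53 in astrocyte-like, −2.67) and Kif9 (−0.56 and 3.72 in microglia-like nuclei, −4.16). The make-up of the subicular-like class differed between the groups, so a shift between its clusters is not excluded for the Xylt1 value there.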

How the results depend on the processing

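Library-size scaling, scaling per nucleus, clusters 0 and 3 alone, the HDACi libraries alone and leaving out 1 library for the class differences were chosen after the data were seen. In DG granule-like nuclei the drug count was within 1.5 times of 7777 in every alternative but the 2 given below. Of 179 pairs of a named gene and a class, RLE scaling and keeping doublets left all 179 with their direction and call, DESeq2 left 146 of 157, the replicate block 172, library-size scaling 163 and scaling per nucleus 136. Where a fit left 1 library in a group, that library was taken to vary like the others. Fewer nuclei, fewer libraries or another threshold change a count by construction, and otherwise the cause was not tested. The stricter nuclei filter gave no value for subicular-like, immature neuron-like and Cajal-Retzius-like nuclei, and the looser filter and the higher resolution gave none for subicular-like nuclei, for lack of nuclei or of a named cluster. In simulated DG granule-like counts 44% of genes changed 1.5-fold were recovered. The simulation changed 50 genes at each fold among 15532, while 50.1% of genes were called in the data. How often such changes are missed in the data is therefore not known from it.

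Genes called with the inhibitor numbered 3432 in CA1-like, 1232 in CA3-like, 64 in Cajal-Retzius-like, 711 in OPC-like, 736 in astrocyte-like, 219 in immature neuron-like, 1600 in interneuron-like, 826 in microglia-like, 1681 in oligodendrocyte-like and 387 in subicular-like nuclei with DESeq2. With at most 40 nuclei per class and library the values were 582 in CA1-like, 573 in CA3-like, 943 in DG granule-like, 665 in OPC-like, 153 in astrocyte-like, 237 in immature neuron-like, 323 in interneuron-like, 268 in microglia-like, 39 in oligodendrocyte-like and 222 in subicular-like nuclei. At an adjusted p of 0.01 the values were 3744 in CA1-like, 1866 in CA3-like, 15 in Cajal-Retzius-like, 1333 in OPC-like, 1181 in astrocyte-like, 235 in immature neuron-like, 2143 in interneuron-like, 2349 in oligodendrocyte-like and 357 in subicular-like nuclei. Per nucleus the value was 120 in Cajal-Retzius-like nuclei. With limma-voom the value was 143 in Cajal-Retzius-like nuclei. With the replicate block edgeR called 0 in Cajal-Retzius-like nuclei, with 609 at an unadjusted p below 0.05, 9 by DESeq2 and 76 by limma-voom. With all 6 libraries the values were 523 in Cajal-Retzius-like, 1120 in immature neuron-like and 2029 in subicular-like nuclei. With at least 200 genes and no mitochondrial limit the value was 171 in Cajal-Retzius-like nuclei. At an adjusted p of 0.1 the values were 527 in Cajal-Retzius-like, 1018 in immature neuron-like and 1604 in subicular-like nuclei. In cluster 3 alone the value was 4193 in DG granule-like nuclei. With at least 1000 genes and at most 1% mitochondrial UMIs the values were 1213 in OPC-like, 1444 in astrocyte-like and 0 in microglia-like nuclei, the last by edgeR with 1161 at an unadjusted p below 0.05, 86 by DESeq2 and 0 by limma-voom. At the higher resolution the value was 1420 in astrocyte-like nuclei. With thinned counts the value was 188 in subicular-like nuclei. With 1 library left out the ranges were CA3-like 1874 to 2511 (lowest without Veh-CFC replicate 2), Cajal-Retzius-like 37 to 398 (lowest without Veh-CFC replicate 1), OPC-like 1339 to 1701 (lowest without Veh-CFC replicate 2), astrocyte-like 1428 to 2016 (lowest without HDACi-CFC replicate 2), immature neuron-like 272 to 636 (lowest without Veh-CFC replicate 2), microglia-like 1436 to 2201 (lowest without Veh-CFC replicate 2) and subicular-like 269 to 1529 (lowest without Veh-CFC replicate 2).

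Genes called for CFC against Context numbered 4400 in CA1-like, 2826 in CA3-like, 380 in OPC-like, 519 in astrocyte-like, 290 in immature neuron-like, 2408 in interneuron-like, 624 in microglia-like, 1333 in oligodendrocyte-like and 306 in subicular-like nuclei in the HDACi libraries alone. With DESeq2 the values were 2648 in CA3-like, 20 in Cajal-Retzius-like, 237 in OPC-like, 392 in astrocyte-like, 118 in immature neuron-like, 2087 in interneuron-like, 453 in microglia-like, 994 in oligodendrocyte-like and 625 in subicular-like nuclei. In the vehicle libraries alone the values were 60 in Cajal-Retzius-like, 445 in OPC-like, 619 in astrocyte-like, 266 in immature neuron-like and 640 in microglia-like nuclei. With doublets kept the value was 1902 in astrocyte-like nuclei. With 1 library left out the ranges were CA3-like 2843 to 4416 (lowest without Veh-Context replicate 1), Cajal-Retzius-like 16 to 144 (lowest without HDACi-Context replicate 1), OPC-like 378 to 910 (lowest without HDACi-Context replicate 1), astrocyte-like 517 to 1028 (lowest without Veh-Context replicate 1), immature neuron-like 93 to 534 (lowest without HDACi-Context replicate 1), interneuron-like 2365 to 3920 (lowest without Veh-Context replicate 1), microglia-like 540 to 1124 (lowest without HDACi-Context replicate 1), oligodendrocyte-like 1312 to 1768 (lowest without HDACi-Context replicate 1) and subicular-like 577 to 1886 (lowest without Veh-Context replicate 1).

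Genes whose drug effect differed from DG granule-like nuclei numbered 61 in CA1-like, 81 in CA3-like, 198 in OPC-like, 41 in astrocyte-like, 5 in immature neuron-like, 58 in interneuron-like, 33 in microglia-like, 7 in oligodendrocyte-like and 103 in subicular-like nuclei with at most 40 nuclei per class and library. With 1 library left out the ranges were CA1-like 1702 to 2236 (lowest without Veh-CFC replicate 2), CA3-like 1205 to 1654 (lowest without HDACi-CFC replicate 2), Cajal-Retzius-like 23 to 146 (lowest without Veh-CFC replicate 2), OPC-like 680 to 968 (lowest without Veh-CFC replicate 2), astrocyte-like 368 to 938 (lowest without HDACi-CFC replicate 2), immature neuron-like 20 to 105 (lowest without Veh-CFC replicate 2), interneuron-like 1057 to 1817 (lowest without Veh-CFC replicate 2), microglia-like 769 to 1247 (lowest without Veh-CFC replicate 2), oligodendrocyte-like 1455 to 1838 (lowest without HDACi-CFC replicate 2) and subicular-like 124 to 645 (lowest without Veh-CFC replicate 1).

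The percentage of called genes with the CFC sign in Context was 95.9 in all nuclei, 97.2 in CA1-like, 98.3 in CA3-like, 80 in Cajal-Retzius-like, 97.7 in DG granule-like, 97.5 in OPC-like, 99.5 in astrocyte-like, 96.8 in interneuron-like, 97.7 in microglia-like and 95.8 in oligodendrocyte-like nuclei with at least 500 UMIs. With at least 20 UMIs the values were 95.5 in CA3-like, 96 in DG granule-like, 93.7 in OPC-like, 94.8 in astrocyte-like, 94.3 in interneuron-like, 91 in microglia-like and 91.1 in oligodendrocyte-like nuclei. With doublets kept the values were 93.5 in OPC-like, 95.2 in astrocyte-like and 96 in oligodendrocyte-like nuclei.

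The difference in share of nuclei, in percentage points, was 3.21 in CA1-like, 1.62 in CA3-like, −1.09 in microglia-like, −3.7 in oligodendrocyte-like and −0.362 in subicular-like nuclei with at least 1000 genes and at most 1% mitochondrial UMIs. With doublets kept the values were 1.65 in CA3-like and 0.252 in astrocyte-like nuclei. With at least 200 genes and no mitochondrial limit the value was 0.135 in endothelial-like nuclei.

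Of 263 list and class pairs, all nuclei together among the classes, 135 were called, 0 with an estimated correlation (camera, lowest adjusted p 0.49), 71 with the directional and 218 with the mixed test of fry, and 97 to 152 with 1 library left out. In DG granule-like nuclei the test of other deacetylases and sirtuins pointed down without a low-count filter (adjusted p = 0.974) and with fry (0.179), and that of circadian genes without the filter (0.984) and without HDACi-CFC replicate 1 (0.958, range 0.759 to 0.991). Log2 fold changes turned negative with library-size scaling for Hdac3 (−0.12), Hdac8 (−0.23), Arc (−0.20) and Homer1 (−0.19), and per nucleus for Hdac3 (−0.27), Hdac8 (−0.38), Arc (−0.34), Homer1 (−0.34), Ncoa1 (−0.12), Slc17a7 (−0.11) and Gabrb1 (−0.035). Arc ranged from −0.30 (without Veh-CFC replicate 1) to 1.23. For CFC against Context, Fos was −0.29 in the vehicle libraries alone, −0.04 without HDACi-CFC replicate 1 and −0.30 to 0.95 with 1 library left out. Nr4a1 was 0.0797 in the HDACi libraries alone and −1.06 to 0.0782 (without Veh-Context) with 1 left out, and Bdnf 0.0155 in the vehicle libraries alone and −0.20 to 0.0139 (without HDACi-Context) with 1 left out.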

Other observations

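Some genes changed the same way in every class tested. Of 1874 genes tested in all 11 classes, 8 were called higher in all of them: Fam49a (mean log2 fold change 1.40), Glp2r (1.26), Camk2a, the alpha subunit of a calcium-dependent kinase (1.24), Grin2a, an NMDA receptor subunit (1.18), Dclk1 (1.17), Sybu (1.11), Jmjd1c (1.03) and Nav2 (0.846). Called lower in all of them were 6 genes, among them Trim37 (−1.58), Odf2 (−1.40), Atad2b (−1.13) and Vti1b (−0.972). In at least 9 classes 93 genes were higher and 32 lower, where independent classes would give 0.198 and 0.000317, but the classes share their libraries. Free RNA was not measured, so RNA from neurons is not excluded as the origin of neuronal transcripts such as Camk2a and Grin2a in glia-like nuclei. These genes and those of the next paragraph were named after their values were seen.

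Long intergenic noncoding RNAs had a median log2 fold change above 0 in all 11 classes with TMM scaling (0.174 to 0.866), but from −0.0734 to 0.603 with library-size scaling, below 0 in CA3-like, interneuron-like, immature neuron-like and Cajal-Retzius-like nuclei. The group was not tested. In DG granule-like nuclei their median was 0.363, with 319 of 1127 called higher and 83 lower, and in microglia-like nuclei it was 0.866, with 101 of 188 higher and 10 lower. With library-size scaling the medians were 0.000338 and 0.603. In DG granule-like nuclei 1123 called genes went the opposite way in at least 1 other class and 27 in at least 5, of which 23 fell in DG granule-like nuclei. Asap1 fell there (−0.88) and rose in 6 classes, and Sh3rf1 (−1.33), Lrrc8d (−1.33), Jam3 (−1.16) and Xylt1 (−1.05) fell there and rose in 5. Mysm1, a histone H2A deubiquitinase, rose (0.44) and fell in 6 classes.

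Of the tests in the next 4 paragraphs, those on genes per nucleus, on Cmss1 and AY036118 as a batch, on Pde1c and on the label were chosen after the result was seen. The others were fixed before.

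DG granule-like nuclei had fewer genes in HDACi-CFC at equal depth. At 3000 UMIs per nucleus the gap was −221 genes against a larger replicate gap of 9, which argues against depth. With the 50 genes with the most UMIs left out it was −234 against 15, which argues against a few abundant genes. It does not reach a broader shift toward well-expressed genes, which was not tested. With TMM scaling the highest expression quintile had 1683 genes higher and 555 lower, and the middle quintile 478 and 1214. Of 8 glial and vascular marker lists 4 had a higher UMI share in both HDACi-CFC libraries and 1 a lower one. This met the bound set against more RNA from glia and vessels in Veh-CFC, but cannot decide it, because genes of glia also rose in their own classes. With library-size scaling the median was 0.278 for myelin genes in oligodendrocyte-like and 0.386 for astrocyte genes in astrocyte-like nuclei. Dock10 is also on both the oligodendrocyte and the DG granule marker lists. Cajal-Retzius markers went from 372.98 and 412.42 CPM in Veh-CFC to 270.05 and 279.0 CPM in HDACi-CFC, and immature neuron markers from 245.08 and 251.61 to 178.69 and 168.15 CPM. In their own classes these markers rose (0.564 and 0.559 on the log2 scale). If all of the marker UMIs came from such cells, their RNA would fall by at most 225 of 3000 UMIs, which would change the number of genes by fewer. Taken the same way, the fall was below the bound set for it in 1 of 8 other classes, astrocyte-like nuclei, with 23.8 of 1000 UMIs against a gap of 48.8 genes. The gap was also present within these 2 classes. At 1000 UMIs Cajal-Retzius-like nuclei had 715 and 716 genes in Veh-CFC and 634 and 645 in HDACi-CFC. Immature neuron-like nuclei had 749 and 745, and 696.5 and 691. RNA of the class itself would not be foreign there, but RNA of the other class was not excluded. More RNA from other cells in Veh-CFC, these 2 types among them, and a change within the nuclei cannot be told apart from these values. An effect of the drug stays open as a hypothesis, and other technical causes, such as nuclei quality, were not tested.

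Lists of neuronal and of activity genes had medians above 0 in DG granule-like nuclei with TMM scaling. The median of the 6 neuronal lists together was 0.363 against 0.300 for random lists matched on expression level, at percentile 96.4, within the middle 95%, so a trend with expression level may account for it. Matched on length too it was at percentile 97.1, again within the middle 95%, and a length trend cannot be told apart from none because the level-matched value had not been outside. The 2 activity lists together had a median of 0.620 against 0.0529, at percentile 100 of level-matched and 100 of level- and length-matched lists, which argues against both trends. Of all 23 lists, 7 lay above the middle 95% of level-matched lists and 2 below it. Among the 7 were also the astrocyte (percentile 100), myelin (99.8) and ribosomal protein lists (99.8), so this position was not particular to activity genes. For the activity lists an effect of the drug stays open, with scaling as a limit: their median was 0.104 per nucleus.

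Some genes were higher in the Context than in the CFC libraries. Cmss1 and AY036118 were called lower in CFC, with the same sign in both drug arms, in 24 of 24 pairs of a gene and a class (the 11 classes and all nuclei together), which conditioning and a library batch predict alike, so the 2 cannot be told apart. The excess of Cmss1 in Context, divided by that of Gm42418, varied by 1.24 times between classes, consistent with 1 common source of reads, whereas that of Pde1c varied by 10.9 times, which argues against that source for Pde1c. The ratio for AY036118, not among the tests set, varied by 1.27 times, so a shared source of reads goes with the values of both Cmss1 and AY036118. Whether that source differed through a batch or through conditioning cannot be told apart. Conditioning was not tested as a biological explanation.

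The library labelled Veh-Context is described as HDACi in another field. In DG granule-like nuclei 96.7% of 6912 genes called after conditioning had the same sign in HDACi-Context over this library, and 90.8% to 97.1% in the 11 classes. An HDACi library under this label, or an exchange of the 2 Context libraries, would not show these signs, so the values argue against both. Its 1710.5 genes per nucleus at 3000 UMIs lay between the 1707 and 1716 of Veh-CFC, against 1489.5 to 1522 in the HDACi libraries. Of genes called for conditioning in the HDACi libraries alone, 96.7% of 4326 and 96.2% of 4435 had the same sign in Veh-CFC replicate 1 and replicate 2 over this library, which argues against an exchange with a Veh-CFC library. A vehicle library from outside the series stays open. So does an exchange of vehicle tissue with Veh-CFC before the libraries were made, since a library batch could give the same signs. A whole pool exchanged with HDACi tissue would be an HDACi library under this label, which the values above argue against. No biological explanation was tested.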
